A study of Mus musculus with 2 samples.

How the data were processed

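Gene expression was measured in mouse haematopoietic stem and progenitor cells that carry no lineage markers and are positive for Sca-1 and c-Kit (LSK cells). One population came from bone marrow of mice at 8 weeks of age and the other from fetal liver at embryonic stage E14.5. There was 1 array per group. Per the labels' protocols, freshly isolated cells were stained and sorted by flow cytometry, and total RNA was extracted with a column kit. Per the labels' protocols, 20 ng of RNA with a 1-colour spike-in mix was then amplified and labelled with Cy3. The labels give a strain, C57BL/6, for the bone marrow sample, and none was used here for the fetal liver sample.

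Per the file headers, the deposited spot intensity values were written by Agilent Feature Extraction 10.7.1.1, which subtracted the background and removed the spatial trend within each array. They are linear processed signals with no scaling between arrays. Per the file headers, the other columns used here were flags of 0 or 1 for each spot, the median spot and local background intensity, and the software's error of the processed signal. The deposited series value table holds a linear ratio per probe, made by the authors. On the probes printed as 1 spot, that ratio was the processed signal divided by 1 constant per array, 178.6 for bone marrow and 133.9 for fetal liver. The match held within 0.1% for 99.99% of the probes. Its column medians were 0.0589 and 0.0604, and it is neither logged nor centred by gene. How the authors chose the constants is not given in the sources used here. They lie close to each array's 75th percentile.

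Each array held 62976 spots, of which 59305 were not controls, for 55681 probes. Feature Extraction marked 137 bone marrow spots and 122 fetal liver spots as outliers, and these were left out. No spot was saturated. Signals of repeated spots of a probe were averaged. The main values were the log2 processed signal minus the log2 75th percentile of that array, which was a signal of 178.8 for bone marrow and 134.0 for fetal liver. Probes well above background numbered 26376 (47.4%) on the bone marrow array and 25812 (46.4%) on the fetal liver array. The median signal of negative control spots was 2.70 and 2.27, and the lowest signal of a probe well above background was 11.2 and 9.82. The 100 brightest probes held 19.4% and 21.0% of the signal.

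Technical precision was read from 235 probes printed as 10 spots each and well above background on both arrays. The SD of the log2 difference between single spots was 0.14 over these probes, with 0.21 among the dimmest of 3 equal groups and 0.06 among the brightest. The error that Feature Extraction gives for its signals corresponded to a median error of 0.20 per log2 difference between the arrays, and this is the value after ± in the results. These spreads are technical only. The number of arrays limits the precision, and no biological spread can be estimated from 1 array per group. The arrays lay on different slides, so slide and group cannot be told apart. Of 10 spike-in controls, 8 were above background on both arrays. Their median unscaled log2 difference, fetal liver minus bone marrow, was -0.08 (SD 0.17), while the 75th percentiles differed by -0.42. After scaling by the percentile the spike-in controls therefore differed by 0.33. The software's spike-in fit had a slope of 1.02 for bone marrow and 0.997 for fetal liver.

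Gene symbols were taken from the reference gene table (assembly GRCm38.p6) through the accession in each probe's systematic name, without versions. That table was used only for names and for which genes neighbour each other, because the array design uses build mm9, and no coordinates are given. Of 55664 probes left on both arrays, 27226 were named, for 20655 symbols, and 28438 had no symbol here. A gene took the value of its probe with the highest mean signal. Of 3379 genes with more than 1 probe above background, 4 had probes that differed at least 2-fold in opposite directions (Acot3, Flrt3, Zfp27 and Zfp599, named because of that).

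A gene entered the comparison when it was well above background on at least 1 array. Where it was not well above background on the other array, its difference is a bound: the bright signal was set against the higher of the dim probe's own signal and the lowest signal of any probe well above background on that array. Such values are written as at least N-fold. With 1 array per group there is no test across samples, no p-value is given, and genes were counted by the size of their difference, at least 2-fold. Gene lists, 31 in number, and 13 processing alternatives were fixed before the data were examined. The median difference of each list with 3 or more measured members was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. A list stood apart when its median lay outside the middle 95% of them. Intervals of list medians are 95% bootstrap intervals over members (10000 draws). They describe the spread among members, which are not replicates, and not the uncertainty of the difference between the cell populations. Places among random lists likewise describe these arrays and are no test between the groups. Members measured as bounds entered at their bound.

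The genes named were also chosen by a rule set in advance. It took the 15 largest differences in each direction among genes above background on both arrays and the 8 largest bounds in each direction, leaving out model and clone names. It added up to 4 members with the largest differences in each list, and a set of key genes of fetal and adult haematopoiesis. Members named outside this rule are marked as such. Some genes that the rule names are not reported here.

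The alternatives were quantile normalization, scaling by the spike-in controls, equal medians of probes above background on both arrays, intensity-dependent loess, normexp background correction with an offset of 50, and the authors' value table. Others were genes above background on both arrays only, no filter on dim probes, the mean over a gene's probes, a 4-fold threshold, and random lists drawn without matching. Scaling by the 75th percentile of probes above background on both arrays was added after seeing the data. The files hold the median and not the mean spot signal, so normexp used the median spot signal with the median local background, which departs from the plan. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1.

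The counting and list steps were tested on simulated data. Their noise was only the spread between spots of the same probe, and every simulated gene was above background on both arrays. The simulation therefore says nothing on bounds or on false differences from slides, labelling or animals. In a simulated comparison of fetal liver with bone marrow over 12261 genes, all 100 genes given a log2 difference of 1.5 and all 100 given 3 passed 2-fold, and 0 of 12061 unchanged genes did. Among 200 simulated lists of unchanged genes 6% lay outside the middle 95%, and 100% of 20 lists shifted by 0.5 lay above it.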

Results

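Expression profiles of LSK cells, the fraction of blood-forming tissue that holds stem cells and multipotent progenitors, were compared between adult bone marrow (8 weeks) and fetal liver (embryonic stage E14.5), with 1 single-colour Agilent array for each. The comparison asks how this compartment differs between a fetal and an adult site of blood formation. Tissue and age differ together, and by the sex-linked genes given below so does the sex make-up of the samples. Probes well above background made up 47.4% of the bone marrow array and 46.4% of the fetal liver array. There were no replicates, so no difference below has a replicate check. Differences are log2 signal of fetal liver minus bone marrow after scaling each array to its 75th percentile, and the value after ± is the technical error that the image software gives.

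Fetal liver LSK cells had high signals for the fetal RNA-binding proteins Lin28b, Igf2bp1, Igf2bp2 and Igf2bp3, for the chromatin protein Hmga2 and for the imprinted gene Dlk1. Bone marrow LSK cells had high signals for Dntt, the terminal transferase of lymphoid progenitors, for antigen presentation and interferon-stimulated genes, for immediate early genes and for the cell cycle inhibitors Cdkn1a and Cdkn2c. The inhibitor Cdkn1c went the other way, at 3.48-fold higher in fetal liver. Mitotic genes were modestly higher in fetal liver. Kit was at the same level on both arrays (0.01 ± 0.20) and Ly6a, which encodes Sca-1, was 4.85-fold higher in bone marrow. Both proteins were used to sort the cells. The sort selects on protein and does not set the RNA level, so how far it shaped these values is not known.

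Of 13386 genes above background on at least 1 array, 925 (6.91%) were at least 2-fold higher in fetal liver and 1087 (8.12%) at least 2-fold higher in bone marrow. Bounds accounted for 224 and 247 of these. At least 8-fold differences were seen for 75 genes higher in fetal liver and 119 higher in bone marrow. Across the 12258 genes above background on both arrays, Pearson's r was 0.963 and Spearman's rho 0.961, values across genes, which are not independent replicates. The median difference of all measured genes was 0.11 and the SD across genes 0.79. Fetal liver held 46.0% of the 2-fold differences under this scaling and 23.3% when the arrays were scaled by the spike-in controls, which gave 527 genes higher in fetal liver and 1738 higher in bone marrow and moved the median of all genes to -0.23. Spike-in scaling lowers each difference between measured signals by 0.33. With normexp background correction the counts were 380 and 606, and large differences were smaller, with Lin28b at 4.73, Tnfrsf25 at 4.22 and Dntt at -8.96. Folds and bounds below are those of the main setting.

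**Figure D1:**
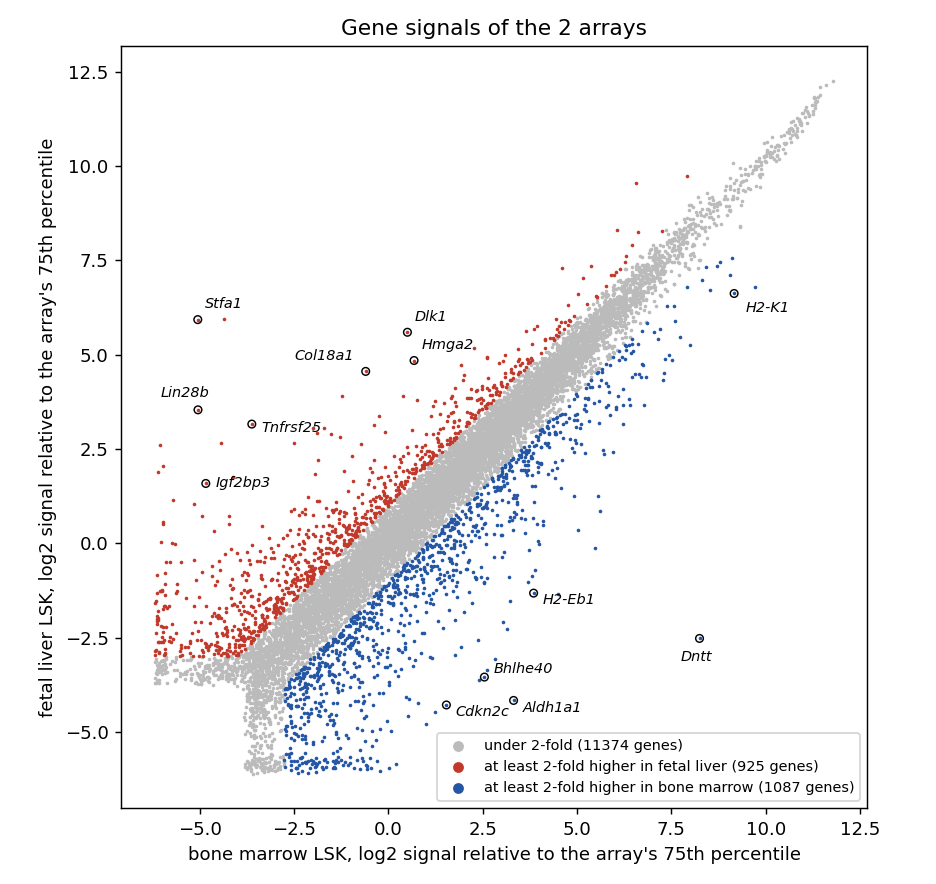
Log2 signal of each of 13386 genes in fetal liver LSK cells (vertical axis) against bone marrow LSK cells (horizontal axis), each relative to its array's 75th percentile. Red points are the 925 genes at least 2-fold higher in fetal liver and blue points the 1087 at least 2-fold higher in bone marrow, while grey points at the lower and left edges lie near background on 1 array.

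The list of Lin28/let-7 axis and oncofetal genes had a median difference of 1.53 (interval 0.57 to 4.17), above all 10000 random lists. Of its 16 measured members 10 were at least 2-fold higher in fetal liver and 0 in bone marrow. Lin28b, which blocks maturation of let-7 microRNAs, was at least 186-fold higher in fetal liver, a bound of 7.54 on the log2 scale. Its other probe gave a smaller bound of 3.27. The list median was 0.79 under normexp. Igf2bp1 was at least 66.4-fold and Igf2bp3 at least 48.0-fold higher, and Igf2bp2 was measured on both arrays at 32.8-fold higher (5.04 ± 0.22). Hmga2, a let-7 target, was 17.97-fold higher (4.17 ± 0.20), with signals of 3857 in fetal liver and 286 in bone marrow. Arid3a, a transcription factor of B lymphopoiesis, was 8.19-fold higher (3.03 ± 0.20). Sox17, a regulator of fetal stem cells, was at least 5.08-fold higher by the main value, from a dim signal of 42.6, its other probe giving a bound of 1.32. Lin28a, named although outside the rule for named genes, differed by 0.18.

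Imprinted growth genes had a median of 1.24 (0.61 to 1.80), above all random lists, with 10 of 14 measured members at least 2-fold higher in fetal liver and 0 in bone marrow. Dlk1, a Notch ligand relative, was 34.1-fold higher (5.09 ± 0.20), and Cdkn1c, a cyclin-dependent kinase inhibitor, 3.48-fold. Plagl1, a zinc finger transcription factor, was 6.28-fold higher (2.65) by its brightest probe, but its 4 probes ranged from -0.38 to 2.65. Igf2, a fetal growth factor, was at least 7.52-fold higher from a signal of 63.0. Spike-in scaling left 7 members at least 2-fold higher. Among embryonic globins, Hbb-bh1 was at least 10.5-fold and Hbb-y at least 6.47-fold higher in fetal liver at signals of 87.7 and 54.3, and Hba-x was not well above background on either array.

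Erythroid lineage genes had a median of 0.80 (-0.09 to 1.497), above all random lists, but went both ways. Of 19 measured members, 7 were at least 2-fold higher in fetal liver and 2 in bone marrow. The adult beta-globin genes led, with Hbb-bt 7.95-fold higher (2.99 ± 0.20), Hbb-b2 7.50-fold and Hbb-bs 5.49-fold. These near-identical genes can share probe signal, so their separate values are uncertain. Rhd, a blood group protein, was 4.39-fold higher. Car1 and Tfr2, outside the naming rule, were higher in bone marrow, at -1.66 and -1.46.

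Genes of mitosis were higher in fetal liver by a median of 0.75 (0.56 to 0.99), above all random lists. All 27 measured members had positive differences, and 8 were at least 2-fold higher, while under spike-in scaling 24 were positive and 0 passed 2-fold. The largest were Plk1, a mitotic kinase, at 1.24 ± 0.20, Ccnb1, cyclin B1, at 1.23, Kif20a, a kinesin of cytokinesis, at 1.22, and Bub1, a checkpoint kinase, at 1.17. Mki67, a proliferation marker, differed by 0.56. The list of S phase and DNA replication genes lay within the random lists at 0.29 (percentile 91.5), with 1 of 29 members, Ccne1 (cyclin E1) at 1.73, at least 2-fold higher in fetal liver. The other probe of Ccne1 was at 0.66. Ribosome biogenesis genes had a median of 0.48 (0.28 to 0.58), with 1 of 28 at least 2-fold higher, the nucleolar protein Gnl3 at 1.17. Oxidative phosphorylation genes had a median of 0.39 (0.28 to 0.46), with 47 of 49 positive and 0 at least 2-fold. Both lists lay above the middle 95% of random lists, at percentiles of 99.98 and 99.92. Under spike-in scaling the medians were 0.15 for ribosome biogenesis, with 0 genes at least 2-fold higher, and 0.06 for oxidative phosphorylation, with 27 positive, against -0.23 for all genes.

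Quiescence-associated genes had a median of -0.54 (-1.71 to -0.07), at percentile 0.01, with 10 of 23 measured members at least 2-fold higher in bone marrow and 4 at least 2-fold higher in fetal liver. Cdkn2c, the kinase inhibitor p18, was at least 39.6-fold higher in bone marrow and Cdkn1a, the kinase inhibitor p21, was at -3.67 ± 0.20. Nr4a1, a nuclear receptor, was at -2.92 and Btg2, an antiproliferative factor, at -2.40. Cdkn1c, which is also in this list, was higher in fetal liver, as given among the imprinted genes. Of the 23 members, 9 are also in other lists. Nr4a1 and Btg2 are among the immediate early and stress response genes too, so these lists are not separate evidence.

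MHC class II presentation genes had the lowest median of the 30 lists, -2.98 (-3.53 to -1.44), below all random lists. Of 11 measured members 9 were at least 2-fold higher in bone marrow. H2-Eb1 was 35.95-fold higher (-5.17 ± 0.21), H2-Aa at least 27.0-fold and H2-Ab1 11.6-fold, all class II chains, and Cd74, the invariant chain, was 10.9-fold higher. MHC class I presentation genes followed at -1.82 (-2.49 to -1.25), with 16 of 21 at least 2-fold higher in bone marrow and 0 in fetal liver. H2-Q8 was 57.3-fold higher in bone marrow, and H2-Q7 and H2-Q6 lay at -2.95 and -2.73, values uncertain because probes of this gene family can cross-hybridise. Nlrc5, the class I transactivator, was at -3.79 by 1 probe and at -0.66 by the other. Members outside the naming rule were H2-K1 at -2.54, B2m, the shared light chain, at -1.82, and the peptide transporter gene Tap1 at -2.13.

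All 35 measured interferon-stimulated genes had negative differences, with a median of -0.94 (-1.07 to -0.72), below all random lists. At least 2-fold higher in bone marrow were 14 under the main scaling and 25 under spike-in scaling. Ifi44 was at -3.79, Zbp1, a nucleic acid sensor, at -3.25, and Oas3, an antiviral synthetase, was at least 8.52-fold higher in bone marrow. Ifit3 was at least 5.42-fold higher in bone marrow.

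**Figure D2:**
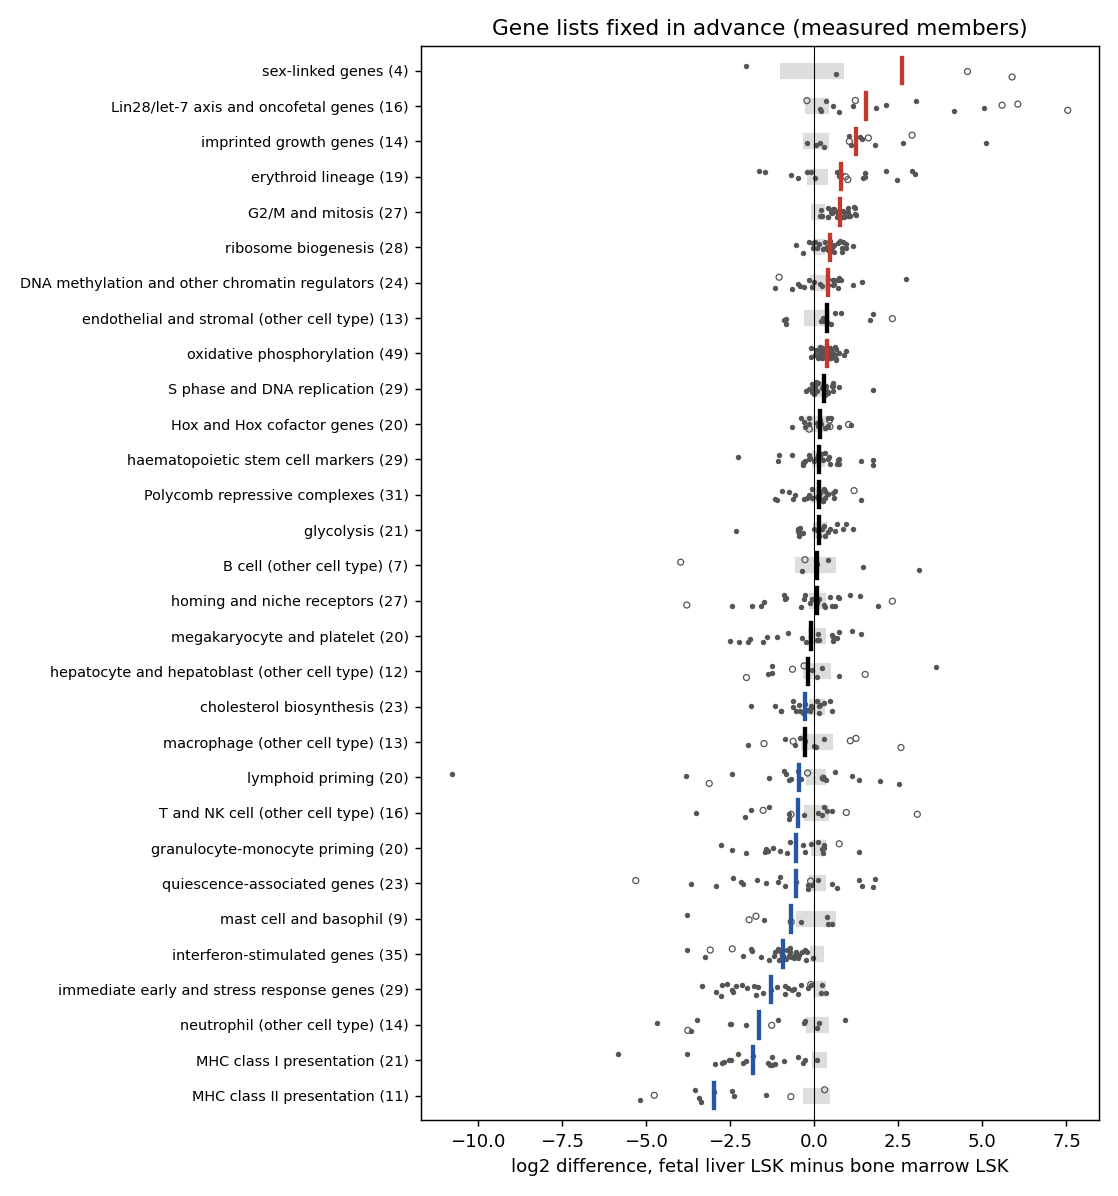
Log2 difference, fetal liver minus bone marrow, of the measured members of 30 gene lists, ordered by median, with the number of members in parentheses. Filled points were above background on both arrays, open points are bounds, vertical bars are list medians (red above, blue below, black within the middle 95% of random lists) and grey bands span that middle 95%, from 2.60 for sex-linked genes to -2.98 for MHC class II genes.

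Immediate early and stress response genes had a median of -1.28 (-2.002 to -0.67), below all random lists, and 16 of 29 were at least 2-fold higher in bone marrow with 0 at least 2-fold higher in fetal liver. Socs3, a feedback inhibitor of cytokine signalling, was at -3.35 ± 0.20, and the nuclear receptors Nr4a1 and Nr4a2 were at -2.92 and -2.78. Junb, an AP-1 subunit, was at -2.75. The members Fos at -0.61, Jun at -0.48 and Dusp1 at 0.23, named outside the rule, were under 2-fold.

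Lymphoid priming genes had a median of -0.44 (-0.86 to 0.30), at percentile 0.11, with members in both directions. Dntt had a signal of 54329 in bone marrow and 23.4 in fetal liver, a 1743-fold difference and the largest among genes above background on both arrays (-10.77 ± 0.25). Blnk, an adaptor of B cell receptor signalling, was at -3.82, and Ly6d, a marker of B-primed lymphoid progenitors, was at least 8.71-fold higher in bone marrow. Ccr9, a thymus homing receptor, was 5.69-fold higher in fetal liver, and Flt3, the receptor of multipotent lymphoid-primed cells, was at -0.89. In all, 4 of 20 members were at least 2-fold higher in fetal liver and 5 in bone marrow, against 2 and 9 under spike-in scaling, where the median was -0.77. Granulocyte-monocyte priming genes had a median of -0.54 (-1.30 to 0.17), below all random lists, with 8 of 20 at least 2-fold higher in bone marrow. The list of neutrophil genes, markers of another cell type, went the same way and further (-1.65), with 9 of 14, and shares Elane with this list. The granule protease genes Ctsg and Elane were at -2.76 and -2.03, Nkg7 at -2.44 and Hp, haptoglobin, at -1.47. Gfi1, outside the naming rule, was the 1 member at least 2-fold higher in fetal liver (1.35).

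Mast cell and basophil genes had a median of -0.68 (-1.94 to 0.40), at percentile 0.855, with 4 of 9 at least 2-fold higher in bone marrow, led by the basophil protease Mcpt8 at -3.79. Among genes above background on both arrays only, that median was -0.004 and lay within the random lists. Megakaryocyte and platelet genes lay within the random lists at -0.08, with 7 of 20 at least 2-fold higher in bone marrow and 2 in fetal liver. Itga2b, the platelet integrin CD41, was at -2.50, and Slc14a1, a urea transporter, at -2.24. Taking the mean over each gene's probes moved that list to -0.37, below the random lists.

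Haematopoietic stem cell markers lay within the random lists, with a median of 0.15 and 3 of 29 members at least 2-fold higher on each side. Tek, the angiopoietin receptor, was at 1.76 and Ctnnal1, alpha-catulin, at 1.75, while Slamf1 (CD150) differed by 0.73 ± 0.23, Procr by -0.32, Cd34 by -0.13 and Cd48 by 0.51. Hox and Hox cofactor genes were within the random lists at 0.18, with Hoxb6 at 1.09 and 13 of the 33 genes dim on both arrays. Homing and niche receptors were within at 0.07, with 4 of 27 at least 2-fold higher in fetal liver and 5 in bone marrow. Under spike-in scaling these were 3 and 8. Alcam, an adhesion molecule, was at least 13.8-fold higher in bone marrow, and Cdh5, VE-cadherin, was at least 5.01-fold higher in fetal liver from a dim signal.

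Polycomb genes lay within the random lists at 0.15. Ezh1, a histone H3 methyltransferase, was 2.24-fold higher in bone marrow (-1.16 ± 0.20, its probes from -1.16 to -0.66) and Mtf2, a partner of the Polycomb complex, was at 1.38, while Ezh2 differed by 0.29 ± 0.20. DNA methylation and other chromatin regulators lay above the random lists at 0.41 (-0.08 to 0.60), at percentile 99.5. Dnmt3b and Dnmt3a, the de novo DNA methyltransferases, were at 2.72 and 1.43, and Smarca2, a chromatin remodelling ATPase, at -1.17. Under spike-in scaling this list had a median of 0.08. Glycolysis genes lay within the random lists at 0.14, where Aldoc, an aldolase, was at -2.33 and Slc2a1, a glucose transporter, at 1.15. Cholesterol biosynthesis genes lay below them at -0.27 (-0.45 to -0.08), at percentile 0.52, with Insig1 at -1.89, and 3 of 23 were at least 2-fold higher in bone marrow. Myc differed by -0.54. Spike-in scaling shifts list and random medians nearly alike, so it can hardly change the side of a list. Under it the medians of 7 lists within the random lists turned negative, and these lists stayed within. They were stem cell markers (-0.18, with 10 positive and 19 negative against 18 and 11), Hox genes (-0.15), homing and niche receptors (-0.26), Polycomb genes (-0.18), glycolysis (-0.19), S phase (-0.04) and B cell genes (-0.24).

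**Figure D3:**
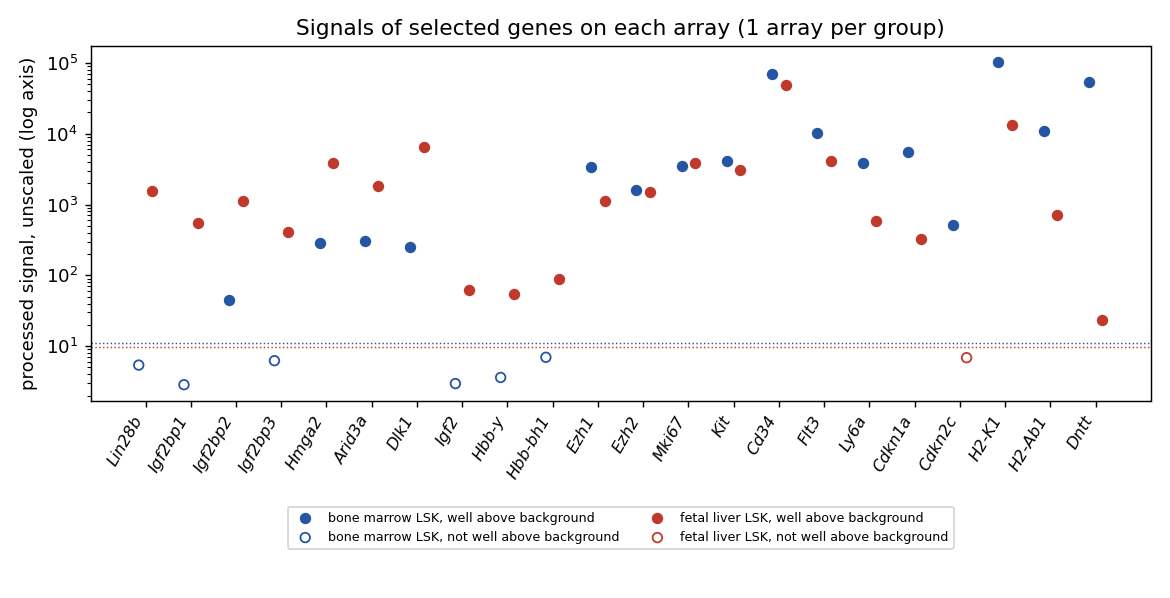
Unscaled processed signal (log axis) of 22 genes on the bone marrow array (blue) and the fetal liver array (red), 1 array per group. Open circles are not well above background, dotted lines mark the lowest signal of a probe well above background (11.2 and 9.82), and Dntt spans the widest range, from 54329 to 23.4.

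Among markers of other cell types, neutrophil genes were higher in bone marrow, with a median of -1.65 (-3.09 to -0.26), below all random lists, and 9 of 14 at least 2-fold. Chil3 was 25.5-fold, Ngp 12.7-fold and Retnlg at least 13.5-fold higher in bone marrow, while the abundant S100a8 and S100a9, named outside the rule, differed by 0.15 and -0.26. T and NK cell genes had a median of -0.50 (-1.35 to 0.29), at percentile 0.26, and lay within the random lists under normexp (-0.08). Ccl5, a chemokine, was at -3.51 and Gzma, a granzyme, was at least 8.37-fold higher in fetal liver. Hepatocyte genes were within the random lists at -0.19, with 14 genes including Alb dim on both arrays. Afp, alpha-fetoprotein, was 2.39-fold higher in bone marrow and Apoc1, an apolipoprotein, 12.4-fold higher in fetal liver. Macrophage genes lay within at -0.27, endothelial and stromal genes at 0.39 and B cell genes at 0.09. In the B cell list Jchain was at least 15.7-fold higher in bone marrow and Bank1 8.67-fold higher in fetal liver. Of the macrophage genes, Fcgr1 was at least 5.98-fold higher in fetal liver, and Plvap, of the endothelial genes, was at 1.65, with its other probe at 0.82. Sex-linked genes had a median of 2.60 (-2.03 to 5.89) over 4 measured members, with the X-inactivation transcript Xist at -2.03 (other probe -1.07) and the Y-linked Eif2s3y and Ddx3y at least 59.1-fold and 23.5-fold higher in fetal liver. Y-linked Uty was above background on both arrays and differed by 0.65, at dim signals of 14.8 and 17.3, with its other probe at 1.52, and Kdm5d was dim on both. Without the filter on dim probes the median was 0.65 and within the random lists. Sex of the animals is not given in the labels used here. Eif2s3y and Ddx3y had signals of 2.61 and 2.82 in bone marrow, not well above background, against 496 and 197 in fetal liver. Xist had a signal of 719 in bone marrow and 132 in fetal liver. These values argue against the same sex make-up in both samples, so sex cannot be told apart from tissue and age.

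The largest differences measured on both arrays also held genes outside the lists. Higher in fetal liver were Tnfrsf25, a death receptor, at 110.2-fold (6.78 ± 0.33), Fn1, fibronectin, at 36.1-fold, Col18a1, a collagen, at 35.8-fold, Grrp1 at 35.2-fold, the chemokine receptor Cxcr3 at 27.9-fold, Tff1, a trefoil peptide, at 27.3-fold and Hif3a at 21.7-fold. Higher in bone marrow were the repressor Bhlhe40 at 68.1-fold (-6.09 ± 0.33), the niacin receptor Hcar2 at 62.9-fold, Npdc1 at 60.02-fold, Myl10 at 48.4-fold, the hexokinase Hk3 at 42.7-fold, Hey1, a Notch target, at 30.6-fold and Klf9 at 26.8-fold. The probes of Cngb1 disagreed, with differences from -4.71 to 0.18. Other probes gave smaller differences of -2.55 for Hcar2 and 2.98 for Hif3a. Among bounds, the stefin A family genes Cstdc5, Stfa1, Stfa3 and Cstdc4 were at least 979-fold, 975-fold, 100.1-fold and 97.0-fold higher in fetal liver, values that members of this family can share through cross-hybridisation. In bone marrow, Aldh1a1, a retinaldehyde dehydrogenase, was at least 136-fold, Gdf15, a stress cytokine, at least 65.1-fold, Sult1a1, a sulfotransferase, at least 31.8-fold and Osm, oncostatin M, at least 23.3-fold higher. Of the genes named above with at least 2-fold differences, Bub1, Ccnb1, Cdh5, Ezh1, Fcgr1, Gnl3, Hoxb6, Ifit3, Kif20a, Ly6d, Plk1, Rhd, Slc2a1, Smarca2, Sox17 and Tek fell under 2-fold under at least 1 alternative setting.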

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

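The results in this part were looked for after the main values were seen, and no explanation was tested for them. Probes with no gene name here carried signal outside the gene comparison. Of 10332 such probes above background on at least 1 array, 571 were at least 2-fold higher in fetal liver and 596 at least 2-fold higher in bone marrow. Of these, 287 and 284 were probes written for chromosome regions without a gene. The largest unnamed differences were 8.84 and -7.89 on the log2 scale. Among 96 external RNA control probes, which are separate from the spike-in probes used for scaling, 4 were above background on both arrays, at similar unscaled signals. The brightest, ERCC-00148_99, had a signal of 125 on the bone marrow array and 120 on the fetal liver array.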

How the results depend on the processing

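Scaling by the 75th percentile of probes above background on both arrays was chosen after the data were seen; the others were planned. The counts of genes at least 2-fold higher in fetal liver and in bone marrow were 527 and 1738 under spike-in scaling, 380 and 606 under normexp, 1673 and 1644 with no filter on dim probes, and 225 and 358 at a 4-fold threshold. The last change follows from the stricter threshold. Without the filter, 20655 genes replaced 13386 and bounds gave way to differences, so both choices changed. Added genes were 596 and 366 of those counts, and 152 and 192 main genes held as bounds newly passed 2-fold. The spike-in change follows from a shift of all genes, while the cause of the normexp change was not tested. Under quantile, equal-median and loess scaling, the authors' value table, genes above background on both arrays, the mean over probes and the added scaling, counts stayed within 1.5 times, from 701 to 934 and from 840 to 1254. Of the 2012 main genes, spike-in scaling shared 80.2%, loess 91.7% and normexp 47.1%. Of 166 named genes 0 reversed direction in 1621 values, and 106 of 138 stayed at least 2-fold under all of these settings. Of 19 lists outside the random lists 16 kept their side. Spike-in, equal-median and the added scaling and the authors' value table shift list and random medians nearly alike. For these the side was almost fixed in advance, so only the other settings could test it. T and NK cell genes came inside under normexp (-0.08) and no filter (-0.09), mast cell genes with both arrays above background (-0.004) and sex-linked genes with no filter (0.65). Macrophage genes then stood below with both arrays above background (-0.35) and megakaryocyte genes with the mean over probes (-0.37). Leaving out saturated spots was not run because no spot was saturated, and slide as a block was not run because each slide held 1 group. No paired analysis was possible because each group had 1 array. Genes near background are limited to bounds.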

Other observations

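All tests and gene families in this part were chosen after the results were seen, apart from the neutrophil, B cell, macrophage and class II lists, which were fixed in advance. Families were grouped by gene symbol and placed among matched random lists as before. Glutathione S-transferases were lower in fetal liver, with a median difference of -0.76 below all 10000 random lists and 8 of 18 genes at least 2-fold higher in bone marrow. Gstt1 was at -3.06 and Gstt3 at -2.09, and Gstm1, Gstm2 and Gstm3, whose probes can share signal, lay between -1.37 and -1.46, although the 3 probes of Gstm2 ranged from -1.37 to -0.35. Kruppel-like factors had a median of -0.50, with 5 of 14 at least 2-fold higher in bone marrow, among them Klf10 at -2.45 and Klf4 at -1.67. Interleukin receptors had a median of -0.35, with 6 of 24 at least 2-fold higher in bone marrow, including Il1r1 at -2.26 and Il1r2 at -2.49, and 2 higher in fetal liver, Il5ra at 1.73 and Il7r at 1.33. Dual-specificity phosphatases had a median of -0.40 and went both ways. At least 2-fold higher were 5 of 19 in bone marrow, with Dusp10 at -3.04 and Dusp5 at -2.03, and 3 in fetal liver, Dusp9 at 1.48, Dusp7 at 1.11 and Dusp3 at 1.04. The medians of these 4 families kept their direction under quantile and loess scaling. Spike-in scaling lowers measured differences, so it could only make these negative medians more negative and is no check of their direction.

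Higher in fetal liver were Gimap GTPases, regulators of lymphocyte survival, at a median of 0.80 and of 0.47 under spike-in scaling, with 3 of 8 at least 2-fold higher. Gimap8 was at 1.60, and Gimap4 at 2.59 by its brightest probe, its 3 probes ranging from 1.03 to 2.59. Chemokine receptors had a median of 0.59, close to the upper limit of random lists (0.58), and of 0.26 under spike-in scaling. That median is the value of Ccr8, a bound from a dim signal of 12.7. Of 9 receptor genes, 3 were at least 2-fold higher in fetal liver, with Cxcr3 at 4.80, and 1 in bone marrow, Cxcr4, the receptor for a bone marrow niche chemokine, at -1.84. Smaller shifts of the median were seen for aminoacyl-tRNA synthetases (0.49, 1 of 16 at least 2-fold higher), nuclear pore proteins (0.45, 2 of 19) and mitochondrial ribosomal proteins (0.42, 0 of 77). Proteasome subunits had a median of 0.33, near the upper limit of random lists (0.32), with 0 of 38 at least 2-fold higher in fetal liver and 2 in bone marrow, Psmb9 at -1.39 and Psmb8 at -1.16. Under spike-in scaling, which moved all genes to -0.23, these 4 medians were 0.16, 0.12, 0.08 and 0.001. Cytosolic ribosomal proteins lay within the random lists at 0.19 and turned to -0.14 under spike-in scaling. Other families placed in the same way also lay within the random lists. They were chaperonin subunits, hnRNP and SR splicing factors, Toll-like receptors and the TNF receptor superfamily. Collagens, aldehyde dehydrogenases, Schlafen genes, and sialic acid and lectin receptors did so too.

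Of 8 stefin A genes, intracellular cysteine protease inhibitors, 7 were at least 2-fold higher in fetal liver, all as bounds, with a family median of 5.87. Stfa1 had a signal of 8178 in fetal liver and 5.38 in bone marrow. Mature neutrophils in the fetal liver sort, which express these genes, would raise other neutrophil genes too. The neutrophil list was lower in fetal liver at -1.65 (interval -3.09 to -0.26). That argues against a larger share of neutrophils in the fetal liver sort than in the bone marrow sort. S100a8 and S100a9 were at 0.15 and -0.26, and some neutrophils in the fetal liver sort are not excluded. It stays open whether one family transcript bound by probes of several members set all 7, since no probe sequences were used, whether a strain difference between the mice plays a part, since 1 of the samples has a strain in its labels, or whether the genes differ with tissue or age, which was not tested.

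The lower MHC class II signals of fetal liver might come from mature B cells or macrophages in the bone marrow sort, which lineage depletion should remove. Such cells would bring their own transcripts, but the lower of the B cell and macrophage list medians was -0.27, and both intervals, -0.36 to 1.45 and -0.63 to 0.29, lay above the class II interval of -3.53 to -1.44. The intervals describe the spread among genes only, and that of the B cell list rests on 7 of 16 members, with 6 others dim on both arrays. Within that limit, these values argue against such cells as the whole cause. Single members went with them, as Jchain was at least 15.7-fold, Spic 3.91-fold and Vcam1 at least 2.81-fold higher in bone marrow. Others went the other way, as Bank1 was 8.67-fold, Cr2 2.72-fold and Fcgr1 at least 5.98-fold higher in fetal liver. Of all these, Spic, Vcam1, Cr2 and Fcgr1 fell under 2-fold under some alternative setting. A small share of such cells in the bone marrow sort stays open. The highest median of the class II list under any setting was -2.49, so the choice of setting does not account for the lower signals. Spike-in scaling lowers measured differences by only 0.33 and could hardly have removed a median of -2.98. The outcome of that scaling was therefore nearly fixed in advance. Other antigen-presenting cells, a difference between slides, which cannot be told apart from the groups, and the age and tissue of the cells stay open. So do a strain difference between the mice, as for the stefin A genes, and a difference in sex.

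Genes with 2-fold differences in the same direction lay next to each other along chromosomes more often than in a chance order of genes. Among the 13386 measured genes there were 14 runs of 4 or more neighbours, against a median of 1 and at most 3 in 100 shuffles within chromosomes. The longest held 9 genes of the MHC class II region, from H2-DMb1 to H2-Eb1 and including Tap1 and Psmb8, all higher in bone marrow. Other runs were the stefin A genes, the beta-globin genes, the Gstm genes, and Mcpt8, Ctsg, Gzmc and Gzmb. Probes shared by neighbouring copies of one gene family may account for part of this and cannot be told apart from shared regulation here, since no probe sequences were used. Most runs hold at least 2 genes with related symbols, which need not be near-identical copies. The longest run also joins unlike genes, such as Tap1, Psmb8 and H2-Eb1, which are not copies of one gene. By symbols cut at the first digit, 3 of the runs hold no 2 genes with one stem, and by the first 3 letters only 1, Phldb2, Plcxd2, Cd96 and Retnlg.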
